A study of Piromyces finnis with 38 samples.

How the data were processed

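RNA-seq libraries of Piromyces finnis were labelled by growth substrate or by the time after glucose was added to a culture on reed canary grass. The labels give 38 samples, which were grouped by those labels. The deposited table was made with RSEM version 1.2.6, per the submitters' processing notes; the aligner and the reference transcripts are not given in the sources used here. The table has 38 value columns, named only by a running number in the style that the labels' protocol uses for its samples, and the protocol does not say which titled sample has which number. The values were read to see their unit. The numbers of the columns of each unit were then set beside the places of the titled samples in the list. Although the table was deposited as FPKM, its columns are of 2 kinds: in 23 columns most values above 0 were exactly whole as printed, as mostly holds for estimated counts, and in the other 15 columns at most 1.1% were. One of the 23 columns is nearly empty, with 14 values above 0, all of them whole. The remaining columns of that kind hold 7687 to 14822 values above 0, of which 87.3% to 92.0% were whole. Values of the 2 kinds are not comparable as deposited. The name of each column was compared with the title, description and characteristics of every sample after removing punctuation and case. Neither the order of the columns nor the values in them were used to assign a column to a sample. All 38 columns were left out of any comparison, so depth per sample is not given, and none of the tests planned before the data were examined was run. Looser ways of matching the names were tried as alternatives. All 27140 rows are named by transcript assembly IDs that the table pairs with no gene name, and no reference annotation was used here, so the gene lists fixed in advance were not applied.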

Results

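The series sampled RNA from whole cultures of Piromyces finnis, an anaerobic fungus of the herbivore gut that grows on plant biomass, for sequencing of its transcripts. The labels describe 38 samples in 13 groups. Of these samples, 18 were labelled by the carbon source alone and fall into 6 groups, and 20 were labelled by the time after glucose was added to a culture on reed canary grass and fall into 7 groups.

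The carbon sources ranged from soluble sugars to intact plant material. Glucose, a monosaccharide, had 4 samples, and fructose, another monosaccharide, had 1 sample. Cellobiose, the glucose disaccharide released from cellulose, had 3 samples. Avicel, a microcrystalline cellulose, had 4 samples, and filter paper, a further form of nearly pure cellulose, had 2 samples. Reed canary grass, a lignocellulose in which cellulose lies with hemicellulose and lignin, had 4 samples. This part of the design addresses how transcript levels differ between carbon sources. Fructose, with 1 sample, has no replicate in the design. The labels' protocol assigns 2 of the numbered samples to a standard Illumina library preparation and 36 to another preparation, without giving their titles. If that numbering follows the order in which the samples are listed, which the labels do not state, the 2 are 1 glucose sample and 1 reed canary grass sample. Samples of one group may therefore differ in library preparation.

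The pulse part of the design addresses how transcript levels change when glucose reaches a culture growing on grass, the setting in which catabolite repression is studied. The labels place 4 samples at 0 min, 2 at 20 min, 3 at 40 min and 4 at 60 min. Later sampling is at 210 min with 2 samples, at 420 min with 2 samples and at 1680 min with 3 samples. The labels do not say whether samples of one group came from separate cultures.

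No transcript level is reported for any substrate or time. The deposited table has 38 value columns, and 0 of them carry a name that equals a title, description or characteristic of a single sample. Which column belongs to which culture is therefore not stated by the labels, and no difference between substrates or between times was tested. The columns also hold 2 kinds of value, with 23 columns of mostly whole numbers and 15 of mostly fractional ones, which are not comparable as deposited. The sample titles split into the same numbers, with 23 titles made of the letter B and a number and 15 others. The 23 titles cover all 20 pulse samples and 3 substrate samples. Those 3 are 1 Avicel sample, the only fructose sample and 1 filter paper sample. The columns of mostly whole numbers are those numbered 3 to 25, and the others are numbered 1, 2 and 26 to 38. In the order in which the samples are listed, the 23 titles also hold places 3 to 25. This match rests on the order of the list and on the values, neither of which was used to assign columns. If the 2 splits are the same, the kind of value largely follows the pulse and substrate parts of the design. In that case the Avicel group and the filter paper group would each also hold both kinds of value. A column of mostly whole numbers is nearly empty, with 14 values above 0, where the next fewest is 7687. Its sample is not known, so the group sizes given above count a sample with almost no data in a group that cannot be named. The 27140 rows carry transcript assembly IDs with no gene names, so no gene is named.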

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

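Both alternatives were chosen after seeing the column names. A looser rule allowed a name to contain a label, or a label to contain the name, with at least 4 characters shared. It matched 0 of the 38 columns to a single sample. Titles of the letter B and a number are shorter than 4 characters, so that rule could not match a column by them. The other titles share no wording with the column names, which were already known. By titles, the 0 was therefore fixed in advance and is not a separate test. Comparing only the number in the column name with the number in a sample title matched 10 columns to one title each, while 13 columns shared their number with several titles and 15 with none. That rule was not used, because the titles number their samples in more than one series and the column numbers name no series. The alternatives planned for the expression tests were not run, because no column was assigned to a sample.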
